A study of Mus musculus with 2 samples.

How the data were processed

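The series holds 2 Drop-seq libraries of medulloblastoma cells from hGFAPcre;Ptch c/c mice. One was taken at postnatal day 12 (P12) and the other at postnatal days 24 to 30 (P24-30), with 1 library per age. Tumours were dissociated with TrypLE and collagenase I, red blood cells were lysed and the 3′ ends were sequenced on an Illumina HiSeq, per the labels' protocols. CASAVA and the mouse build mm10 are named in the submitters' processing notes. The aligner, the counting tool, the gene annotation, the number of animals and the choice of barcodes are not given in the sources used here.

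The P12 file as deposited holds whole-number counts per gene and 12-base barcode, with 6000 barcodes and 24858 genes. The labels do not say whether these counts were collapsed by molecular barcode, and they were taken as UMIs here. The P24-30 file as deposited holds natural log values, the log of 1 plus 10000 times a gene's share of its cell's UMIs, with 4991 cells and 19714 genes. In that file 100% of the 6195642 values above 0 turned back into whole numbers within 0.001, so the UMIs of each gene and cell were recovered from the natural log values the authors deposited. Its column names carry 16 tags, G1 to G16, that no label explains. The files share 16055 gene names, and 489 more were matched through older symbols in the RefSeq synonyms, for 16544 genes in both. Of these, 16255 have a position in GENCODE vM21 on mm10.

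Cells were kept with at least 500 UMIs and at most 20% mitochondrial UMIs. This removed 9 P12 barcodes for few UMIs and 268 for mitochondrial UMIs, and 146 and 49 at P24-30. Predicted doublets (scrublet, run per library within scanpy) were removed, but the caller marked only 1 P12 cell and 3 P24-30 cells, 0.0175% and 0.0626%, which is too few for this step to have worked. Doublets can therefore remain in any class. After filtering, 5722 P12 cells and 4793 P24-30 cells remained.

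Cells of both libraries were clustered together on log-normalised UMIs of 2000 variable genes, with 30 principal components, 15 neighbours and Leiden resolution 1, seed 1. The 13 clusters were named from fixed marker lists of 21 cell types, by the mean log2 fold of a type's markers over the other cells (pseudocount 20 CPM). A glial or immune name needed a mean of at least 2.5 with at least 3 raised markers (log2 of at least 1), and a neuron-like name a mean of at least 0.75. A cluster without a glial or immune name was set apart when its median depth was under 0.5 of the library's and its top genes were also rarely seen. The latter means that the share of its cells with a UMI of a top 10 gene had a median under 10% over those genes. These naming thresholds were set after the clusters had been seen, and the rule for setting apart was changed once. The planned granule-lineage class was replaced by a main population, that is all clusters left after the glial, immune, mixed and set-apart ones. The reason is that 1 large cluster had Hes1 and Slc1a2, markers of other types, among its top 10 genes and none of the granule lineage, so it failed the marker check. Another main-population cluster (62 P12 and 1222 P24-30 cells), led by Lmbrd1, Zfp715 and Spats2l, scored highest as erythroid, at 3.23 with 4 raised markers. It was not named so because only glial, immune, vascular and neuron-like names were given, and 2323 of its 2433 erythroid-marker UMIs at P24-30 and 306 of 310 at P12 lay in 1 cell each.

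For each age comparison, UMIs were summed over the kept cells and scaled to CPM, UMIs over the library's total on the usual scale. Ratios are P24-30 over P12, with exact conditional 95% intervals (Clopper-Pearson on the split of the summed count) that cover counting error only. The median gene was itself lower at P24-30, so ratios and log2 medians are given relative to it unless stated. With 1 library per age there are no tests, no standard errors and no counts of changed genes. A gene at 0 was set to a floor of 3 counts in its library. Shares of cells carry exact Clopper-Pearson 95% intervals, and for a share of 0 the limit given is 3 cells over the number of cells. Cycling cells and cells with a UMI of a factor were counted after each cell had been thinned to 500 UMIs. On simulated libraries with 200 changed genes, the intervals held the true ratio for 95.6% of 11476 genes at the depth of the main population and 95.7% of 12109 at that of the whole library. In the main population, 96% of genes changed 1.5-fold and 100% of those changed 2-fold were recovered. In the whole library these were 88% and 96%. The simulated counts held counting error alone, so coverage near 95% follows from how they were drawn. These figures check the calculation and not spread between cells or differences in counting between files.

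The named genes follow a rule fixed, like the lists, comparisons and filters, before the data were examined. Among genes with at least 50 UMIs over both libraries, the 12 with the highest and the 12 with the lowest ratio were named, ranked by the interval bound nearest to 1. Mitochondrial, ribosomal protein and sex-linked genes were left out and given as groups. For other classes with at least 50 cells in each library, the 4 highest and 4 lowest were named. For each fixed list, the 2 members at each end were named. Ptch1, Olig2, Sox2, Mycn, Aurka, Yap1, Gli1, Atoh1, Mki67, Xist and Ddx3y were named always. The text prints most but not all of the genes that the rule and the stricter ranking give. Because the genes this rule ranked highest share sequence with other genes, a stricter ranking was added after their values had been seen, in 3 forms. The form reported takes protein-coding genes of at least 2 exons with at least 20 UMIs in each library (5 in microglia-like cells), no shared sequence, no overlap with another gene and at most 10% of a library's UMIs in 1 cell (30% in microglia-like cells). The minimum per library removes genes that nearly vanished in 1 library. The other forms lacked that minimum, and form 1 also the exon rule, and were still led by gene copies or by genes with few P12 UMIs, such as Gm5148 and Kcp. In the main population the reported form shares 1 of its 12 highest and 5 of its 12 lowest genes with form 2, and 0 and 4 with form 1. Shared sequence means that a 50-base word from the last 400 bases of a transcript, taken every 10 bases, also occurs in a transcript of another gene in GENCODE vM21. List values over members that share no sequence also leave out members that overlap another gene, are not protein-coding or exceed that limit of UMIs in 1 cell.

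The 20 fixed lists were SHH pathway, Hippo-YAP, Aurora-A and MYCN, S phase, G2 and M phase, Notch, WNT, dissociation and immediate early, interferon response, antigen presentation, disease-associated microglia, chemokine and cytokine, extracellular matrix, glycolysis, oxidative phosphorylation, myelination, glial progenitor factors, synapse, sex-linked, and RNA quality. Between ages, a list's value is the median log2 ratio over members with at least 20 UMIs, with its percentile among 10000 random lists of the same size matched on mean expression. Between classes, it is the list's summed CPM over that of the reference class within a library, leaving out members that serve as markers of the class.

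Alternatives changed the cell filter, doublet removal, clustering, scaling, summing, the member minimum and the thinning depth. Those added after the data had been seen left out members with shared sequence, cells with over 20% of UMIs in 1 gene or the 5% of cells with the highest doublet scores, scaled to genes listed in both files, or took the lists in other main-population cells alone. The closing section gives their effect. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.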

Results

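Single medulloblastoma cells were profiled from mice in which Cre recombinase, driven by a GFAP promoter, removes Ptch1, the receptor that restrains Sonic hedgehog (SHH) signalling. Drop-seq, which captures single cells in droplets and counts messenger RNA molecules by molecular barcodes (UMIs), was run on tumours of postnatal day 12 (P12) and of postnatal days 24 to 30 (P24-30), with 1 library per age. The P12 library had 6000 barcodes and 12265399 UMIs, with a median of 1778 UMIs per barcode (range 1 to 15050) and 1136 genes. The P24-30 library had 4991 cells and 12284458 UMIs, with a median of 2149 UMIs per cell (range 221 to 50361) and 1181 genes. After filtering, 5722 P12 cells (median 1805.5 UMIs) and 4793 P24-30 cells (median 2194) remained. There is no replicate check on any value, and age cannot be told apart from library preparation or from the counting of each file. All intervals cover counting error only.

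Both libraries differed in what their UMIs came from. Ribosomal protein genes, which build the translation machinery, held 14.98% of UMIs at P24-30 and 5.03% at P12. This difference cannot be told apart from how reads of gene copies were counted, as the files list different ribosomal pseudogenes. Mitochondrial genes held 3.20% and 7.98%, with the mitochondrial ribosomal RNA mt-Rnr2 at 6659 CPM at P24-30 and 68914 at P12, where it was most of the share. These shares are over unlike gene sets, with 37 mitochondrial genes listed at P24-30 and 25 at P12. Listed at P24-30 only were, among others, mt-Co3 (46305 UMIs) and mt-Co2 (15832 UMIs). The filter on mitochondrial UMIs used the same gene sets. The nuclear RNA Malat1 was at 6088 and 15643 CPM, and haemoglobin genes held 0.0222% and 0.00929%.

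Ptch1, the targeted gene (chromosome 13, 63508328 to 63573598), was about 10 times lower in the older library than in the younger one. In the main tumour population it fell from 159.8 CPM (1813 UMIs) at P12 to 12.6 CPM (143 UMIs) at P24-30. Relative to the median gene the ratio was 0.0969 (95% interval 0.0811 to 0.115). In the oligodendrocyte-lineage-like, microglia-like and mixed classes together it fell from 39 UMIs to 2, a ratio of 0.0486 (0.00568 to 0.188) before division by the median gene. After thinning to 500 UMIs, 7.77% of main-population cells at P12 had a Ptch1 UMI (426 of 5481) and 0.469% at P24-30 (21 of 4473). Among microglia-like cells, which should lack Ptch1, 3 of 89 P12 cells had one (3.37%), and 0 of 55 at P24-30, which allows a share of up to 5.45%. The median depths before thinning were 1807 and 2240 UMIs in the main population and 2067 and 2133 in microglia-like cells. The P24-30 share therefore cannot be told from that of microglia-like cells, while the P12 level of 159.8 CPM lies above their 45.8 CPM (21.98 to 84.3). Within the main population at P24-30, neuron-like cells had 5.95 CPM (3.40 to 9.66) and the other cells 14.6 CPM (12.2 to 17.4). These values, compared afterwards, argue against background shared alike by all cells as the whole source. The part of the gene that is deleted is not given in the sources used here and both libraries share 1 genotype, so a 3′ tag does not check the deletion.

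Which cell classes the young and the older tumours held was asked by clustering both libraries together. Most cells belonged to a main population of proliferating progenitor-like and neuron-like cells, and small classes carried markers of the oligodendrocyte lineage, of microglia and of a mixture of choroid plexus, astrocytes and vascular cells. The main population held 95.8% of P12 cells (95.2 to 96.3) and 93.3% of P24-30 cells (92.6 to 94.0). Within it, neuron-like cells, marked by Cntn2, Stmn2 and Tubb3 of differentiating granule neurons, made up 13.7% of P12 cells (12.8 to 14.6) and 28.6% of P24-30 cells (27.3 to 29.9). No direction is read from the neuron-like shares, because they became 19.3% and 16.3% when each library was clustered alone. Of the neuron-like clusters, 1 was 94.1% P12 cells and the other 92.2% P24-30 cells. The 7 other main-population clusters held 82.1% of P12 cells and 64.8% of P24-30 cells. In 6 of them cell-cycle genes such as Cenpa, Hmmr, Hells and Mcm6 were among the top 10 genes, and the remaining one was led by Hes1, Mgarp and Rcn3. These clusters also split by library, with 4 at 3.78% to 9.07% P24-30 cells and 3 at 92.6% to 97.53%.

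Oligodendrocyte-lineage-like cells, led by the progenitor genes Ptprz1, Cacng4 and Gpr17, were 1.85% of P12 cells (106 cells, interval 1.52 to 2.24) and 0.918% of P24-30 cells (44 cells, 0.668 to 1.23), and these intervals do not meet. Microglia-like cells, led by the complement genes C1qa, C1qb and C1qc, were 1.56% (89 cells, 1.25 to 1.91) and 1.15% (55 cells, 0.866 to 1.49). The mixture of choroid plexus, astrocyte and vascular cells, led by Ttr, Enpp2 and Rgs5, was 0.804% (46 cells, 0.589 to 1.07) and 1.19% (57 cells, 0.902 to 1.54). Intervals of the microglia-like and mixed classes overlap between ages. With no filter on cells the mixed class was 2.24% at P12 and 2.22% at P24-30, above both of its intervals. The mitochondrial filter removed 77 P12 and 43 P24-30 barcodes with at least 3 markers of astrocytes or Bergmann glia. The shares of the mixed class therefore describe the kept cells and not the tumours. A further 164 P24-30 cells (3.42%) with a median of 834 UMIs and no clear markers were set apart, against 0 P12 cells, which allows a share of up to 0.0524%. Of these small classes, only microglia-like cells had at least 50 cells in each library for an age comparison.

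How expression in the main tumour population differed between the older and the younger library was asked gene list by gene list, and dividing-cell genes stood out. Genes of G2 and M phase, which drive chromosome separation, were lower at P24-30, among them the kinetochore motor Cenpe and the proliferation marker Mki67. Glial progenitor factors such as Olig1 and the stem-cell factor Sox2 were lower too, as were the Notch target Hes1 and the matrix proteoglycans Bcan and Vcan. Synapse genes such as Vamp2, which acts in vesicle release, were higher, and so were interferon-response genes such as Ifi27 and Xaf1. The median log2 ratio of the 11476 genes with at least 50 UMIs was -0.30 in the main population, and the values and counts of higher or lower members that follow are relative to that median gene. The 5th and 95th percentiles before that division were -1.19 and 2.00. The cells compared sat in different clusters at each age, and neuron-like cells, which held less G2 and M phase and more synapse RNA, were 14.3% of the main population at P12 and 30.6% at P24-30, or 20.1% and 17.4% with each library clustered alone.

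The G2 and M phase list had 45 of 52 members lower, with a median relative log2 ratio of -0.46 and a percentile of 0 among random lists. Before division by the median gene its summed CPM was 18702 at P12 and 12466 at P24-30. In oligodendrocyte-lineage-like cells it was 6559 and 4565, and in microglia-like cells 5523 and 3751. The summed CPM thus fell in these classes too, but free RNA of main-population cells was not told apart there from the classes' own expression. Cenpe had a relative ratio of 0.379 (0.364 to 0.395) and Mki67 one of 0.391 (0.380 to 0.403), with 1573 CPM at P12 and 499.8 CPM at P24-30. The highest members were the cyclin kinase subunit Cks2 (5.80) and the chromatin protein Hmgb2 (9.51). These 4 genes share sequence with other genes, and over the 29 members that share none the median was -0.47, again at percentile 0. The S phase list, of genes of the phase in which DNA is copied, had 33 of 41 members lower. Its median was -0.18 at percentile 3.60 (-0.36 at 0.270 over the 22 members that share no sequence). Its lowest members were Atad2 (0.520) and Casp8ap2 (0.533), and its highest the DNA clamp Pcna (1.88) and the histone RNA binder Slbp (2.19), which also share sequence. Atoh1, which sets granule progenitor identity, had a relative ratio of 0.729 (0.672 to 0.790).

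The SHH pathway list, central to this tumour model, had a median of -0.19 and lay at percentile 9.51, with 8 of 14 members lower. Its feedback inhibitor Hhip (0.460, 0.388 to 0.543) was lowest, and the negative regulator Sufu (1.60, 1.33 to 1.93) and the growth-factor binder Igfbp5 (1.56, 1.08 to 2.27) were highest. Gli1, the transcription factor at the end of the pathway, was higher, at 84.2 CPM at P12 and 100.1 CPM at P24-30, a relative ratio of 1.46 (1.34 to 1.60). The Hippo-YAP list, of organ-growth control, had a median of -0.29 at percentile 2.71 (-0.42 at 1.46 over the 9 members that share no sequence), with 9 of 13 members lower, led by the kinase Lats1 (0.460) and the membrane protein Crim1 (0.536). Its highest members were the tumour suppressor Nf2 (1.35, 1.14 to 1.59) and Ajuba (1.30, 0.632 to 2.69). Yap1 itself, with 97 UMIs at P12 and 59 at P24-30, had a relative ratio of 0.747 whose interval holds 1 (0.531 to 1.04).

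The Aurora-A and MYCN list, of a mitotic kinase and the transcription factor it stabilises with its ribosome-making targets, had a median of -0.17 at percentile 11.2, with 10 of 15 members lower. Aurka (0.667, 0.598 to 0.743) and Mycn (0.682, 0.645 to 0.721) were its lowest members, with Mycn at 312 CPM at P12 and 173 CPM at P24-30. Its highest, Odc1 of polyamine synthesis (5.04) and the nucleolar Fbl (30.3), share sequence with other genes. In the 7 members that share none, the median was -0.50 at percentile 1.18. Notch genes, which hold precursors back from differentiation, were lower in 8 of 9 members, with a median of -0.30 at percentile 5.6, and of -0.83 at percentile 0.240 over the 5 members that share no sequence. Hes1 (0.327, 0.288 to 0.372) and Notch1 (0.3397) were lowest, while Dll1 (0.939) and Maml2 (1.01) lay near the median gene. The WNT list had a median of -0.38 at percentile 2.55, with Ctnnb1 (0.619) and Nkd1 (0.719) lowest, Dkk3 at 0.921 and Sp5 at 7.78 (2.29 to 41.0) from 3 and 19 UMIs.

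Glial progenitor factors had 8 of 9 members lower, a median of -0.47 and percentile 0.930, or -0.41 and 3.33 over the 8 members that share no sequence. Olig1 (0.422, 0.386 to 0.461) and the stem-cell factor Sox2 (0.442, 0.307 to 0.626) were lowest, and Sox9 (0.934) and Nfib (1.25), the latter a factor of granule neuron maturation, were highest. Olig2, a factor of oligodendrocyte and progenitor fate, had a relative ratio of 0.721 (0.598 to 0.868), with 27.8 CPM at P12 and 16.3 CPM at P24-30. The extracellular matrix list had a median of -0.51 at percentile 0.370 (-0.72 at 0.220 over 7 members that share no sequence), led downward by the brain proteoglycans Bcan (0.289) and Vcan (0.446), with Col3a1 (1.43) and Lamb1 (1.75, 0.843 to 3.75) at its upper end. Its median before division by the median gene was -0.81, and -0.00439 with no minimum of UMIs per member. The synapse list, with 9 of 11 members higher, had a median of 0.53 at percentile 99.4 (0.80 at 100 over 9 members that share no sequence). Vamp2 (2.07, 1.74 to 2.47) was among the highest, and the synaptic adhesion gene Nrxn3 (0.425) was lowest.

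Interferon-response genes, which answer viral or inflammatory signals, had a median of 1.56 at percentile 99.9, with 6 of 7 members higher. Xaf1 (30.4, 11.5 to 114), which shares sequence, rose from 4 UMIs to 99 and Ifi27 (18.2, 12.2 to 28.5) from 25 to 371, while Ifit2 (0.885) was lowest. The median before division by the median gene was 1.26, and it became 0.21 over members with at least 100 UMIs and 2.45 with no minimum. In antigen presentation the median was 0.03 (-0.27 before division) at percentile 56.8, with B2m (0.587) and Tap2 (0.949) lowest and H2-K1 (1.10) and H2-D1 (1.48) highest. These are parts of the complex that shows peptides to T cells. The sign of the antigen-presentation median thus depends on the division, and no direction is read. For neither interferon response nor antigen presentation was a value over members that share no sequence obtained.

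Within the parts of the main population, set apart only after the values had been seen, some lists no longer stood out. Among the other main-population cells alone, G2 and M phase genes had a relative median of -0.22 at percentile 0.07, with 37 of 52 members lower, glial progenitor factors -0.33 at percentile 3, extracellular matrix -0.38 at percentile 1.71, and synapse genes 0.46 at percentile 97.8. Notch genes had -0.28 at percentile 5.84 and interferon-response genes 1.55 at percentile 99.9. S phase genes had -0.034 at percentile 54.0, the Aurora-A and MYCN list -0.035 at percentile 38.2 and the SHH pathway -0.087 at percentile 27.8. Among neuron-like cells alone, G2 and M phase genes had -0.37 at percentile 0.02, while the SHH pathway stood at 0.51, Notch at 0.65 over 5 members, synapse genes at 0.12 and interferon-response genes at 0.25 over 4 members. Glial progenitor factors (-0.11 at percentile 30.4) and extracellular matrix (0.087 at percentile 66.6, over 3 members) did not stand out there.

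For a further 5 lists the sign of the median depends on the division by the median gene, and for 3 of them also on members that share sequence. Over members that share none, the relative medians were -0.14 (percentile 23.7) for dissociation and immediate early genes, -0.10 (33.6) for glycolysis and -0.034 (71.4) for oxidative phosphorylation, so no direction is read for these 3. Dissociation and immediate early genes, which respond to handling stress, had a relative median of 0.10 (-0.20 before), percentile 64.7, with Atf3 (0.164) and Ier3 (0.442) lowest and Fos (3.68) and the chaperone Hsp90aa1 (6.11) highest. Glycolysis genes had 0.19 (-0.11 before), percentile 93.4, from the glucose transporter Slc2a1 (0.645) and Hk2 (0.826) to Pgam1 (54.1) and Gapdh (101), which share sequence with copies. Oxidative phosphorylation genes had 0.14 (-0.16 before), percentile 80.6, from Cox4i1 (0.850) and Uqcrq (0.871) to Ndufs5 (4.38) and Atp5g1 (7.72), again genes with copies. Disease-associated microglia genes, lipid and lysosome genes of reactive microglia, had 0.22 (-0.08 before), percentile 84.3, from Spp1 (0.475) and Cd9 (0.841) to Lpl (1.53) and Fabp5 (4.03). Myelination genes had 0.30 (-0.01 before), percentile 82.3, from Ugt8a (1.06) and Mbp (1.08) to the myelin protein Cldn11 (2.67), 1 of its 2 highest members. Before division its median became 0.61 over members with at least 100 UMIs and 1.12 with no minimum.

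The sex-linked and RNA-quality lists describe the samples themselves. Xist, the RNA that silences 1 X chromosome in females, had 10682 UMIs at P12 and 10 at P24-30, a relative ratio of 0.00115, and its antisense partner Tsix had 0.00250. The Y-linked genes Ddx3y (2.69, 2.37 to 3.07) and Eif2s3y (2.72) were higher, and the list's median was 0.98 at percentile 99.7. The RNA-quality list had a median of -0.91 at percentile 0.180, with Malat1 at 0.467, Meg3 at 0.606 and Neat1 at 2.61. Its remaining member of 4 is Xist, which differs with sex and lowers this median, so no difference in RNA quality is read from it. Ribosomal protein genes had a median log2 ratio of 3.44 over 117 genes and mitochondrial genes one of 1.40 over 23 genes, before division by the median gene. The P12 file alone lists ribosomal protein pseudogenes such as Rpl14-ps1 (21883 UMIs), Rps13-ps2 (11551) and Rpl3-ps1 (11013). The ribosomal protein value therefore cannot be told apart from how reads of gene copies were counted in each file.

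Among single spliced genes with no shared sequence found near the 3′ end and enough UMIs in each library, a ranking chosen after the values had been seen, Eln, Ptch1 and Syt14 were lowest at P24-30 and Ifi27 and Tubb6 were among the highest. Eln, which encodes elastin (chromosome 5, 134702593 to 134747323), fell from 154.4 to 6.06 CPM, a relative ratio of 0.0484 (0.0375 to 0.0615). Syt14, a synaptotagmin of membrane trafficking, had 0.106, the homeodomain factor Isl1 0.123, the sperm protamine Prm1 0.169 and the radial-glia lipid binder Fabp7 0.186. Mark4 (0.166), Nme7 (0.205), the zinc-finger genes Zfp811 (0.207) and Zfp445 (0.221), and the inflammatory factor Nfkb1 (0.216) were also among the 12 lowest. Ifi27 (chromosome 12, 103434211 to 103440239) was highest at 18.2, followed by the spliceosome genes Mfap1a (10.8) and Mfap1b (9.80), neighbouring copies with nearly equal UMIs (322 and 347 at P12, 2830 and 2770 at P24-30). Only the last 400 bases were searched for shared sequence, so their counts are uncertain. Tubb6, a beta-tubulin, had 10.4 (8.07 to 13.5), the keratin Krt12 10.5, the mitochondrial importer Timm8a1 9.0 and the forkhead factor Foxf2 9.03. The neural crest factor Pax3 (8.06), the ribosome-biogenesis gene Wdr74 (8.19), the zinc transporter Tmem163 (7.56), Gadl1 (6.14) and Mroh2a (5.44) completed the 12 highest.

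**Figure D1:**
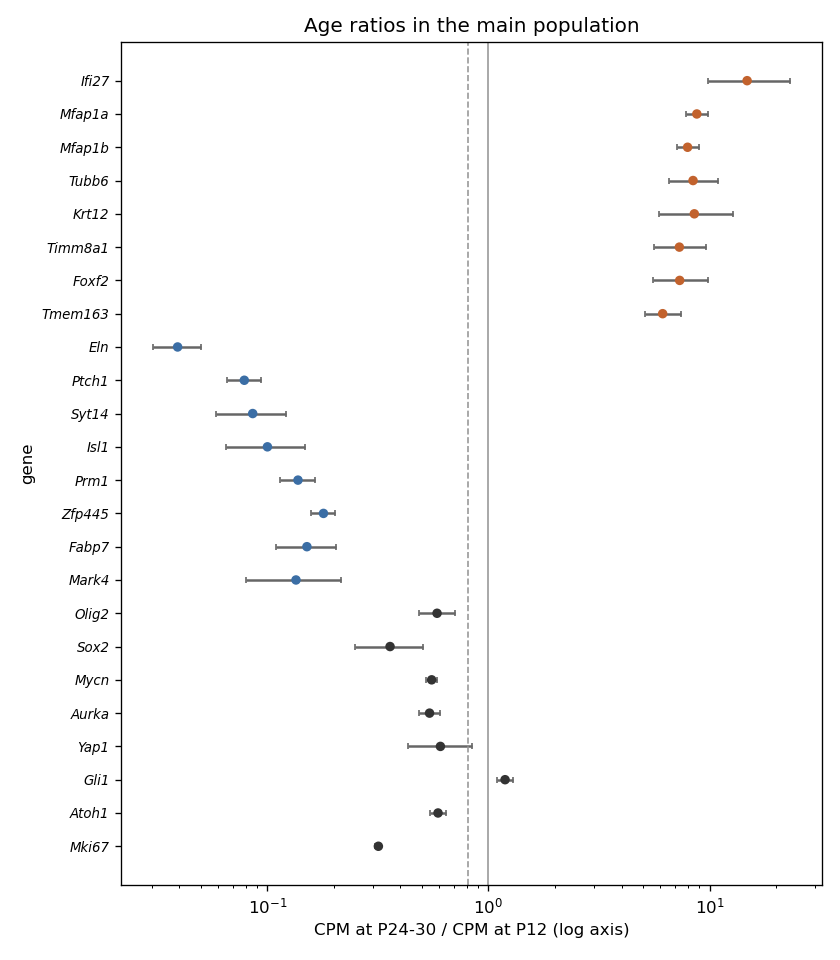
Ratio of CPM at P24-30 to CPM at P12 in the main population on a log axis, with exact 95% intervals, for the 8 highest and 8 lowest genes of the stricter ranking and for 8 genes named in advance. The dashed line marks the median gene and the solid line a ratio of 1; Eln and Ptch1 lie lowest, and Ifi27 lies highest.

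The ranking fixed in advance gave other genes. Its 12 highest were pseudogenes and copies with 1 to 10 UMIs at P12, and all 12 share sequence with other genes, overlap one or are not protein-coding. They include the pseudogene Gm10123 (4 and 38897 UMIs, relative ratio 11942, 4664 to 43833), the histone genes Hist1h2ao (4 and 31500 UMIs) and Hist1h2ap (5 and 31892 UMIs), and the ferritin copy Ftl1-ps1 (1 and 7431 UMIs, 1637 to 360510). The others were Gm7536 (3 UMIs at P12, interval 2867 to 40640), Gm10282, Gm10222, Gm16477, Gm10335, Gm5641, Gm6139 and Gm5619. Its 12 lowest held 4 such genes, and 33.3% of all ranked genes are of that kind. Among the other 8 were Sox11, a factor of neuronal precursors (8098 and 422 UMIs, 0.0640, 0.0579 to 0.0706), the linker histone Hist1h1b (0.0483, 0.0430 to 0.0541) and Eln, beside Gm17018, Ppp2r3d, Ankmy1, Tmem79 and Gpr27. Of the 4 with an overlap, a copy or no protein product, Gm20604 had 517 and 4 UMIs, Sh3bp1 525 and 15 and the small nuclear RNA Gm26226 158 and 5, while the linker histone Hist1h1e had a relative ratio of 0.0901.

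Over all kept cells of each library, the comparison named the same 24 genes as in the main population, and added what the small classes contribute. Interferon-response genes such as Bst2, an antiviral membrane tether, antigen-presentation genes such as Cd74 and H2-Eb1 of class II presentation, and myelin genes such as Mog were higher at P24-30. G2 and M phase genes were lower, as in the main population. Glial progenitor factors had a relative median of -0.48 at percentile 0.110, but of -0.31 at percentile 9.60 over members that share no sequence. The median gene had a log2 ratio of -0.26. Relative to it, the interferon response had 13 of 14 members higher, a median of 2.61 and percentile 100, with Bst2 at 15.97 (7.46 to 40.8), and antigen presentation 10 of 11 members higher, a median of 0.78 and percentile 97.4. Over the 3 interferon members that share no sequence the median was 3.28. No such value was obtained for antigen presentation, or for myelination and glycolysis below. Myelination had a median of 1.21 at percentile 99.5, with Mog at 5.04, but 66.7% of a library's Mog UMIs came from 1 cell, and the median before division, 0.94, became 0.091 over members with at least 100 UMIs. The matrix genes Col3a1 (4.32) and Col1a2 (5.84) had 62.9% and 45.7% in 1 cell. Glycolysis stood at percentile 99.9 with a log2 median of 0.35 before division by the median gene, which turned to -0.055 when each cell was weighted alike. Chemokine and cytokine genes, measured only here and in microglia-like cells, had a relative median of 0.21 at percentile 21.7, from Tgfb1 (0.461, 0.188 to 1.03) to Ccl12 (3.40, 1.96 to 6.18). Of the stricter ranking, the orphan receptor gene Gpr146 was among the highest here, and the matrix genes Mfap2 and Olfml2b and the endocytic kinase Aak1 among the lowest.

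In microglia-like cells, the older library showed more antiviral and antigen-presentation transcripts and less Igf1, a growth factor that microglia release. Bst2 and Ifitm3, membrane proteins that restrict viruses, were higher, and so was the lysosomal gene Psap. Cd300c2, a myeloid surface receptor, and the DNA primase Prim1 were lower. These values rest on 89 cells and 218162 UMIs at P12 and on 55 cells and 138624 UMIs at P24-30, of which 35 cells carry the column tag G8. The median gene had a log2 ratio of -0.21, and values are relative to it. Interferon-response genes were higher in 4 of 4 members, with a median of 2.19 at percentile 98.6. Bst2 had 13.4 (5.69 to 38.5), Ifitm3 8.32 and Ifi27 1.33. Antigen presentation was higher in 8 of 8 members, with a median of 1.82 at percentile 98.7, but its highest genes Cd74 (9.31) and H2-Eb1 (10.5) had 50% and 55% of a library's UMIs in 1 cell, and B2m stood at 1.04. For neither of these lists, nor for chemokine and cytokine genes, was a value over members that share no sequence obtained.

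Of the other lists in microglia-like cells, dissociation and immediate early genes had a median of 1.497 at percentile 99.2 (0.86 over the 4 members that share no sequence), with Hsp90aa1 at 7.76 and Zfp36 at 3.88. Chemokine and cytokine genes had 0.93 at percentile 96.0, with Ccl12 at 5.48 (49.0% in 1 cell) and Ccl3 at 0.807. S phase genes had -0.79 at percentile 2.45, led by Prim1 (0.189, 0.0368 to 0.609, from 29 and 3 UMIs), and G2 and M phase genes -0.39 at percentile 5.28. Over members that share no sequence these were -1.13 at percentile 4.65 and -0.78 at percentile 1.17. Mki67 had 0.382 (0.244 to 0.577). Disease-associated microglia genes had -0.04 at percentile 37.2, from Igf1 (0.262, 0.170 to 0.391) and Cd9 (0.567) to Gpnmb (2.33) and Fabp5 (2.71). The remaining lists lay between percentiles 26.2 and 89.2. Under the stricter ranking Bst2, Gngt2 (5.35), Hmgn5 (4.11) and Psap (2.74, 2.30 to 3.25) were highest and Cd300c2 (0.127, 0.0400 to 0.310), Igf1, Tra2a (0.186) and Psmc3 (0.211) lowest. The ranking fixed in advance gave copies at the top, led by Ftl1-ps1 with 0 and 642 UMIs, at least 337-fold higher before division by the median gene, with Gm7536 (at least 156-fold), Gm10123 and Gm10335. Its lowest were Gm26917 (56 and 0 UMIs, at least 11.9-fold lower), Vps13c (0.0870), the endocytic adaptor Dab2 (0.112) and Cd300c2.

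Within each library, the classes were compared for the networks that the study's title asks about, those at the start of the tumour and its hierarchy. Oligodendrocyte-lineage-like cells held less SHH, Aurora-A and MYCN and cell-cycle RNA than the main population and more of the stem-cell factor Sox2 and the receptor Notch1. They also held more matrix, synapse, interferon and antigen-presentation RNA, in each library. The cyclin Ccnd1 was higher in them and its relative Ccnd2 lower. The SHH pathway list stood at 0.373 of the main population at P12 and 0.486 at P24-30, with Ccnd2 at 0.260 and 0.372. Gli1 stood at 0.120 (0.0145 to 0.435) from 2 UMIs in the class at P12 and at 0.106 (0.00268 to 0.592) from 1 at P24-30. The Aurora-A and MYCN list stood at 0.559 and 0.602, S phase at 0.438 and 0.318 and G2 and M phase at 0.351 and 0.366. Extracellular matrix stood at 8.28 and 7.02, the latter 3.79 with each library clustered alone, and the proteoglycan Bcan at 34.5 and 61.8. Synapse genes stood at 2.11 and 1.79. Interferon response stood at 2.26 and 4.15, antigen presentation at 1.56 and 3.26 and disease-associated microglia genes at 3.05 and 2.56.

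Among single genes in oligodendrocyte-lineage-like cells, Sox2 was at 17.0 (11.4 to 24.7) and 61.8 (35.7 to 104) times its level in the main population, Notch1 at 8.54 (4.50 to 15.1) and 27.9 (9.39 to 69.3) and Ccnd1 at 1.74 and 1.77. Mycn stood at 0.0486 (0.0100 to 0.142) and 0.430 (0.173 to 0.888), and Sox9 and Nfib at 0.238 (0.0874 to 0.520) and 0.202 (0.160 to 0.251) at P12. Hippo-YAP (0.722 and 1.28), Notch (1.07 and 1.64) and WNT (0.937 and 1.26) had an interval that holds 1 in at least 1 library, as did dissociation, glycolysis, oxidative phosphorylation and chemokine genes. Yap1 had 1 UMI in this class at P12, a ratio of 0.591 (0.0148 to 3.37), and 0 at P24-30. The class has 44 cells at P24-30, so genes with few UMIs there carry wide intervals.

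**Figure D2:**
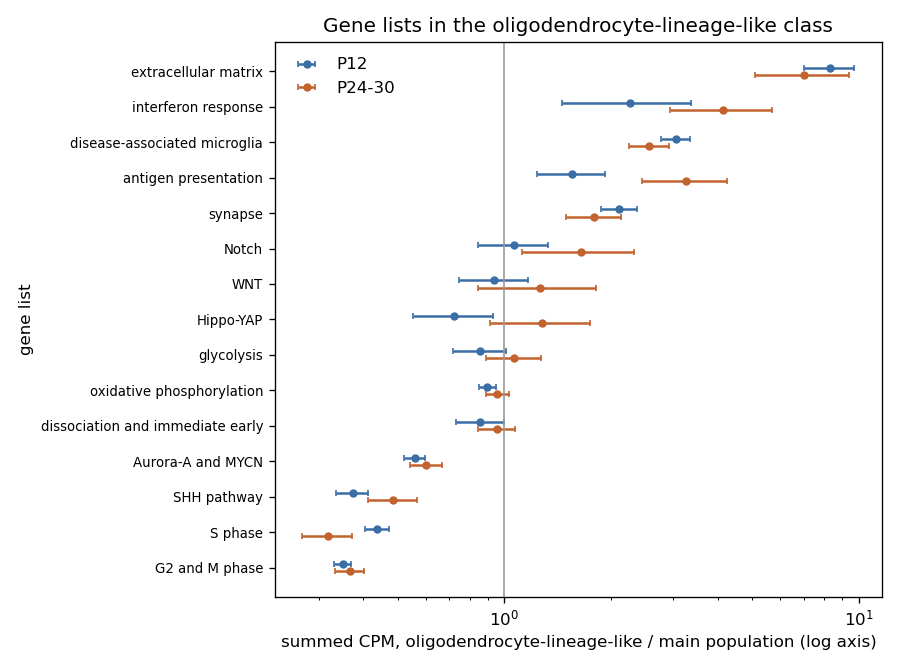
Summed CPM of each of 15 gene lists in oligodendrocyte-lineage-like cells divided by that in the main population, on a log axis, for P12 and P24-30, with exact 95% intervals. With both libraries clustered together, extracellular matrix lies highest in each, and the SHH pathway and both cell-cycle lists lie below 1.

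Neuron-like cells held more synapse RNA and less cell-cycle RNA than the other main-population cells. Synapse genes and the glial and neuronal factor Nfib were higher, and SHH, Notch and cell-cycle genes such as Gli1, Hes1 and Ccnd1 were lower. The synapse list stood at 2.39 at P12 and 1.68 at P24-30, G2 and M phase at 0.170 and 0.177, S phase at 0.279 and 0.322, and the Aurora-A and MYCN list at 0.481 and 0.565. At Leiden resolution 2 the P12 values became 0.517 for G2 and M phase and 0.435 for S phase. The SHH pathway list stood at 0.513 and 0.886, with Gli1 at 0.0871 and 0.208 and Ccnd1 at 0.141 and 0.313. Notch stood at 0.347 and 0.811, with Hes1 at 0.102 and 0.110, but at 0.609 and 0.563 with each library clustered alone, so no difference between libraries is read from it. Hippo-YAP stood at 0.704 and 0.876, WNT at 0.622 and 0.666, antigen presentation at 0.472 and 0.814 and glycolysis at 0.801 and 0.833. Glial progenitor factors stood at 1.38 and 1.43, from Nfib (1.80 and 1.66) and the receptor Egfr (2.37 and 1.43), while Olig1 was at 0.0597 and 0.121. Dissociation genes (1.15 and 1.06) and disease-associated microglia genes (1.18 and 1.26) were slightly higher. Mycn stood at 0.693 (0.610 to 0.784) and 1.01 (0.906 to 1.12), and as other clusterings were not tried for it, no difference between libraries is read. Extracellular matrix genes went opposite ways, at 0.819 and 1.22, the latter 0.711 with each library clustered alone, and oxidative phosphorylation, interferon, chemokine and myelination lists had an interval that holds 1 in at least 1 library.

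Microglia-like cells held far less SHH and cell-cycle RNA than the main population and far more immune RNA. The SHH pathway stood at 0.138 at P12 and 0.236 at P24-30, Aurora-A and MYCN at 0.403 and 0.439, S phase at 0.306 and 0.213, and G2 and M phase at 0.295 and 0.301. Glial progenitor factors stood at 0.163 and 0.180, synapse genes at 0.216 and 0.191 and dissociation genes at 0.711 and 0.570. Chemokine and cytokine genes stood at 162 and 426, disease-associated microglia genes at 93.8 and 63.7, antigen presentation at 32.5 and 63.5, extracellular matrix at 8.74 and 15.8, interferon response at 8.38 and 12.5 and glycolysis at 2.39 and 2.02. At Leiden resolution 0.5 the P12 values became 0.0825 for the SHH pathway and 0.108 for glial progenitor factors, and extracellular matrix at P24-30 became 9.93 with each library clustered alone.

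Whether tumour cells cycled less at the older age was asked with the G2 and M phase list, counting cells with at least 2 of its UMIs at 1 depth. In the main population, where progenitor-like cells divide, fewer cells passed at P24-30 than at P12, and fewer neuron-like cells than other cells passed in each library. The main population had 80.2% of 5481 cells at P12 (79.1 to 81.3) and 66.2% of 4473 at P24-30 (64.8 to 67.6). The other main-population cells had 86.1% and 80.6%, and neuron-like cells 45.0% (41.5 to 48.6) and 33.7% (31.2 to 36.2). Oligodendrocyte-lineage-like cells had 40.6% (31.1 to 50.5) and 31.8% (18.6 to 47.6). Microglia-like cells, in which free RNA and own cycling were not told apart, had 31.5% (22.03 to 42.2) and 34.5% (22.2 to 48.6), which overlap the intervals of oligodendrocyte-lineage-like and neuron-like cells in both libraries. Thinned to 1000 UMIs, neuron-like (75.0%, 71.7 to 78.1) and oligodendrocyte-lineage-like cells (75.5%, 65.8 to 83.6) lay above microglia-like cells (52.3%, 41.3 to 63.2) at P12. At P24-30 their 62.5% (59.8 to 65.1) and 55.0% (38.5 to 70.7) overlapped the 49.1% (35.1 to 63.2) of microglia-like cells. With neuron-like cells weighted as at P12, the difference between libraries in the main population was 6.31 percentage points, against 14.0 as counted. Over 8 clusterings the weighted difference ran from 4.61 to 15.3 points, the latter with each library clustered alone, so no effect of makeup is read. Without thinning the main population had 97.1% and 93.2%, and no share of cells is read as the share in cycle.

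**Figure D3:**
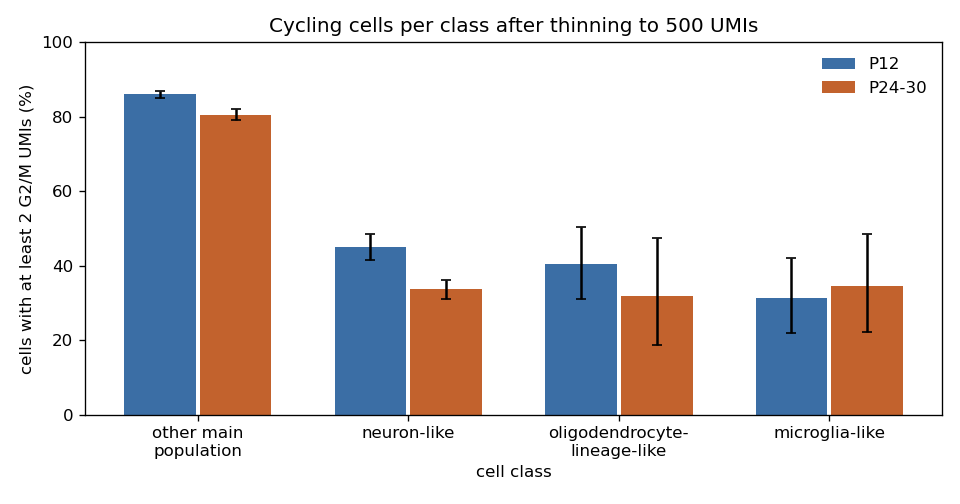
Percent of cells with at least 2 UMIs of the G2 and M phase list after thinning to 500 UMIs, for 4 classes in each library, with exact 95% intervals. Of the other main-population cells 86.1% pass at P12 and 80.6% at P24-30, and of microglia-like cells 31.5% and 34.5%.

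Which cells carried the factors under study was asked as the share with a UMI at 500 UMIs per cell. Mycn, a transcription factor downstream of SHH, and Atoh1, of granule progenitors, were seen in more main-population cells at P12 than at P24-30, and so was Aurka, a mitotic kinase. Mycn was seen in 14.3% (13.4 to 15.2) and 8.61% (7.80 to 9.47), against 4 of 89 (4.49%) and 1.82% of microglia-like cells, which were taken to lack these factors and to show background. Their intervals for Mycn (1.24 to 11.1 and 0.0460 to 9.72) lie below the main-population share at P12 and overlap it at P24-30. Atoh1 was seen in 6.50% and 4.09%, Aurka in 3.28% and 1.70% and Gli1 in 4.03% (3.53 to 4.59) and 4.65% (4.05 to 5.31). Both Atoh1 and Gli1 were seen in 0 of 89 microglia-like cells at P12 and in 1 of 55 at P24-30 (1.82%, 0.0460 to 9.72). In CPM over all UMIs, the main population lay above microglia-like cells at P24-30 for Mycn (172.7, 165 to 181, against 7.21, 0.183 to 40.2), Gli1 (100.1, 94.3 to 106, against 14.4, 1.75 to 52.1) and Atoh1 (83.5, 78.3 to 89.0, against 14.4, 1.75 to 52.1). Aurka lay above them at P12 (84.9, 79.6 to 90.4, against 22.9, 7.44 to 53.5) and at P24-30 (45.9, 42.1 to 50.1, against 7.21, 0.183 to 40.2). The median depths of both classes are those given with Ptch1. Olig2 was seen in 1.24% (0.965 to 1.57) and 0.782% (0.546 to 1.09) of main-population cells and in 33.0% and 20.5% of oligodendrocyte-lineage-like cells. Among neuron-like cells at P12 it was seen in 0 of 784 (median 1432.5 UMIs), which allows up to 0.383%, against 1.45% of the other main-population cells (median 1889). Sox2 was seen in 0.529% and 0.112% of the main population and in 10.4% and 13.6% of oligodendrocyte-lineage-like cells. Yap1 was seen in 0.274% and 0.156%. Olig2 and Yap1 were seen in 0 microglia-like cells, which allows up to 3.37% at P12 and 5.45% at P24-30, and Sox2 and Aurka in 1 of 89 (1.12%, 0.0284 to 6.10) and 0 of 55. Neither these limits nor CPM separate the main-population levels of Olig2, Sox2 and Yap1 from those of microglia-like cells. At P12, CPM of neuron-like and other main-population cells, compared afterwards, argue against free RNA shared alike by all cells as the whole source. In neuron-like cells Olig2 had 0.813 (0.0206 to 4.53) against 31.0 (27.7 to 34.7), and Sox2 0 (up to 2.999) against 12.4 (10.3 to 14.7). Yap1 had 2.44 (0.503 to 7.13) against 9.29 (7.51 to 11.4). At P24-30 the intervals of Olig2 and Sox2 also lay apart, while those of Yap1 (1.28 to 5.86 and 4.37 to 7.71) overlapped.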

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

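Every test in this part was chosen only after the result was seen, except the split of P12 cells by Xist and Y-linked UMIs for the 24 most extreme genes of the stricter ranking.

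Extracellular matrix genes drew attention because they went opposite ways in the 2 libraries: in neuron-like cells the list stood at 0.819 of the other main-population cells at P12 and at 1.22 at P24-30. Whether these differ was not tested, and the P24-30 value turned to 0.711 when each library was clustered alone.

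The unexplained column tags of the P24-30 file drew attention because tag G8 held 35 of the 55 microglia-like cells, and all 35 cells with that tag were of this class. The barcodes removed for mitochondrial UMIs drew attention because many carried at least 3 markers of astrocytes or Bergmann glia. These were 28.7% of the removed P12 barcodes (77 of 268) and 87.8% of the removed P24-30 barcodes (43 of 49), against 4.14% and 3.92% of kept cells.

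All 12 genes with the highest age ratios in the main population share sequence, overlap another gene or are not protein-coding, but whether reads shared between genes were kept in the P24-30 counts and dropped from the P12 counts cannot be told apart from other reasons, because the shared sequence of these same genes prompted the explanation. The 12 lowest hold 4 such genes, which does not bear on it either, since reads kept only at P24-30 raise a ratio, and what lowered these genes stays open. Of the 24 most extreme genes of the stricter ranking, 16 had enough UMIs and 4 differed between P12 cells with Y-linked UMIs and with Xist, at ratios of the first to the second of 1.23 for Ptch1, 1.40 for Syt14, 1.39 for Mroh2a and 0.495 for Isl1, against 8.53% of the 8358 ranked genes with enough UMIs. These differences are smaller than those between ages in the same genes (ratios of 0.0969, 0.106, 5.44 and 0.123), and for Ptch1 and Syt14 they go the other way, but animals of 1 sex cannot be separated and the count lies between the bounds of 12 and 4 set in advance, so differences between individual tumours cannot be told apart from age for these genes. Age itself, the difference the design names, stays open and untested.

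The lower share of cycling cells in the main population at P24-30 is argued not to come from fewer UMIs per cell there, because the median depth at P12 minus that at P24-30 was -433 UMIs. Without thinning the share was still lower at P24-30 (97.1% and 93.2%), though nearly all cells pass there. The depths were known and cells had been thinned to 1 depth, so this outcome was fixed beforehand. Counting differences in the list members that share sequence are argued against by the 22.5 percentage points found over members that share none. Counting differences in other genes change each cell's total before thinning, which this does not test. For sex, the difference between P12 cells with Xist and with Y-linked UMIs was -0.0753 points, and the counting intervals allow at most 4.57 points. Main-population cells with a Y-linked UMI and no Xist passed at 80.5% at P12 (77.3 to 83.5) and at 68.6% at P24-30 (66.2 to 71.0). This difference among cells of 1 sex argues against sex as the whole cause. A part for sex stays open, since these intervals cover cells and not animals, whose number per sex is not given. More neuron-like cells at P24-30 are argued against as the whole cause by the 5.47 points left among the other main-population cells (4.49 to 13.9 over 8 clusterings, with intervals that did not meet in any), but a part is left open, since their share of the main population was 14.3% and 30.6% as reported and 20.1% and 17.4% with each library clustered alone, and the difference with neuron-like cells weighted as at P12 was 6.31 and 15.3 points. More free RNA of cycling cells in the P12 library cannot be told apart, because the microglia-like share at P12 minus that at P24-30 was -3.08 points and its intervals (22.03% to 42.2% and 22.2% to 48.6%) leave room for the 10 points this cause would need, and cycling of microglia-like cells themselves is not excluded. Other microglia-like values go with this cause. The list's summed CPM was 5523 at P12 and 3751 at P24-30. Its relative median log2 ratio was -0.39 at percentile 5.28, and -0.78 at percentile 1.17 over members that share no sequence. Age, a part for sex, differences between individual tumours and differences in library preparation stay open, as none could be settled with 1 library per age.

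Olig2 UMIs occurred in the main population, 315 at P12 and 185 at P24-30. If they came from oligodendrocyte-lineage cells, as free RNA or doublets, their partner Sox10 would be there in the ratio of that class, at 145 and 149 UMIs. Only 1 and 5 Sox10 UMIs were found, at most 3.36% of that number (upper ends of the intervals 3.84% and 7.85%), which argues against that source in both libraries. Expression of Olig2 by some main-population cells is a candidate explanation that was not tested further, and no biological group of the design bears on it.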

How the results depend on the processing

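The alternatives that leave out members with shared sequence, cells with over 20% of UMIs in 1 gene or the 5% of cells with the highest doublet scores, CPM over genes listed for both libraries, and lists in other main-population cells alone, were chosen only after the results were seen. No paired analysis was possible because each age has 1 library. A value counts as the same within its 95% counting interval, and a list's median within the median width to either side of its members' log2 intervals. Of 2162 values recomputed, 1897 stayed the same by this measure, 261 moved and 4 reversed. For every change below, the cause was not tested unless a cause is stated.

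The 4 reversals are these. The log2 median of glycolysis genes in the whole library, before division by the median gene, turned from 0.35 to -0.055 with the mean over cells. Between neuron-like and other main-population cells at P24-30, the extracellular matrix list turned from 1.22 to 0.711 with each library clustered alone. The oxidative phosphorylation list turned from 1.02 to 0.978 with each library clustered alone and to 0.994 without cell-cycle and immediate early genes.

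Shares of oligodendrocyte-lineage-like and microglia-like cells stayed within their intervals under all 9 alternatives tried for them. Neuron-like shares at P12 and P24-30, 13.7% and 28.6% as reported, became 12.7% and 22.3% with at least 1000 UMIs, 10.2% and 22.7% with no cell filter, 12.0% and 30.9% with predicted doublets kept and 11.4% and 26.2% at resolution 0.5. They became 19.3% and 16.3% with each library clustered alone, which turns the direction between ages. At resolution 2 the P12 share was 15.96%, and without cell-cycle and immediate early genes the P24-30 share was 32.4%. The mixed class became 2.24% and 2.22% with no cell filter, and 0.897% at P24-30 with each library clustered alone. Keeping the predicted doublets adds back 4 cells, so its changes come from a new clustering and not from those cells.

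Single-gene ratios between ages held under nearly all alternatives. In the main population 675 of 695 values stayed the same and in the whole library 441 of 463, and most that moved did so by centring, which subtracts the median gene by construction. Centring sets the median of all genes to 0, so it gives no value for that result. Centred, the main-population medians were -0.19 for the SHH pathway, -0.17 for Aurora-A and MYCN, -0.18 for S phase, -0.46 for G2 and M phase and -0.47 for glial progenitor factors. The values in the rest of this paragraph are medians before division by the median gene, reported on that scale as -0.466 for Aurora-A and MYCN, -0.485 for S phase and -0.761 for G2 and M phase. With CPM over genes that are not mitochondrial, ribosomal protein or haemoglobin, Aurora-A and MYCN stood at -0.37 and G2 and M phase at -0.67. With members that share sequence left out, Aurora-A and MYCN stood at -0.80 and S phase at -0.66 (-0.50 and -0.36 relative to the median gene). In other main-population cells alone, Aurora-A and MYCN stood at -0.37 and G2 and M phase at -0.55 (-0.035 and -0.22 relative to the median gene). The interferon median, 1.26 as reported, became 0.21 over members with at least 100 UMIs and 2.45 with no minimum, so it rests on genes with few UMIs.

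The lists that differ between neuron-like and other main-population cells kept their side of 1 in each setting for the 4 lists named next, with sizes that moved. The SHH pathway (P12, then P24-30) stood at 0.481 and 0.943 with predicted doublets kept, 0.454 and 0.855 at resolution 0.5, 0.710 and 0.753 with each library clustered alone, and 0.485 and 0.985 without cell-cycle and immediate early genes. Aurora-A and MYCN stood at 0.459 and 0.599, 0.452 and 0.551, 0.560 and 0.484, and 0.463 and 0.628 in these settings, and at 0.567 at P12 with resolution 2. G2 and M phase stood at 0.153 and 0.184, 0.155 and 0.169, 0.180 and 0.161, and 0.164 and 0.191, and at 0.517 and 0.190 with resolution 2. Hippo-YAP stood at 0.787 and 0.791 with each library clustered alone. Glial progenitor factors stood at 1.27 and 1.61 with each library clustered alone, on the same side of 1 as reported.

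Shares of cycling cells depend on depth and on the minimum by construction. At P12 and P24-30, the main population had 93.2% and 83.3% thinned to 1000 UMIs, 97.1% and 93.2% not thinned, 69.0% and 53.4% with at least 3 UMIs and 69.6% and 47.1% with members that share sequence left out. Neuron-like cells had 75.0% and 62.5%, 87.2% and 83.3%, 23.7% and 15.6%, and 28.6% and 16.7%. Oligodendrocyte-lineage-like cells had 75.5% and 55.0% thinned to 1000 UMIs and 89.6% and 75.0% not thinned. The share was lower at P24-30 in each of these settings. Microglia-like cells had 52.3% and 49.1% thinned to 1000 UMIs and 75.3% and 76.4% not thinned.

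Shares of main-population cells with a UMI of a factor also grow with depth by construction. Thinned to 1000 UMIs, they were 13.9% and 0.983% for Ptch1, 2.28% and 1.49% for Olig2, 1.03% and 0.366% for Sox2, 26.6% and 15.9% for Mycn, 6.80% and 3.59% for Aurka, 0.936% and 0.480% for Yap1, 7.58% and 8.39% for Gli1 and 12.2% and 8.02% for Atoh1. Not thinned, they were 25.5% and 3.02% for Ptch1, 4.25% and 3.55% for Olig2, 2.10% and 0.984% for Sox2, 43.0% and 32.2% for Mycn, 13.2% and 8.72% for Aurka, 1.55% and 1.21% for Yap1, 14.3% and 18.9% for Gli1 and 22.2% and 16.9% for Atoh1. Depth limits the precision of the microglia-like and oligodendrocyte-lineage-like comparisons, which rest on 138624 and 94193 UMIs at P24-30.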

Other observations

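The values in this part were chosen after they had been seen, and no test was run on them.

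Markers of Purkinje cells, the output neurons of the cerebellar cortex, were frequent among the barcodes removed for mitochondrial UMIs. At least 3 such markers occurred in 53.1% of these barcodes at P24-30 (26 of 49, median 1767 UMIs) and in 6.72% at P12 (18 of 268, median 1243.5 UMIs), against 0.271% and 0.0699% of kept cells.

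The P12 library held cells of both sexes. Of its kept cells, 3156 had an Xist UMI and no Y-linked UMI, 703 a Y-linked UMI and no Xist, and 62 both. At P24-30, 17 Xist UMIs stood against 2193 Y-linked ones. Within the P12 main population, the amino-acid stress genes Nupr1 (6.77-fold) and Asns (2.35-fold), the calcium-binding gene Cabp1 (3.74-fold) and Efcab5 (4.40-fold) were higher in cells with Xist. Of these, Nupr1, Cabp1 and Efcab5 had only 4, 6 and 4 UMIs in cells with Y-linked UMIs. The cell-division gene Depdc1b (3.55-fold), the cartilage enzyme gene Csgalnact1 (2.85-fold) and Rflna (2.07-fold) were higher in cells with Y-linked UMIs. All were picked as the extremes of a ranking, and 8.53% of ranked genes with enough UMIs differed between these cells. How many animals were pooled is not given in the sources used here.

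Column tags of the P24-30 file went with cell class. Of 528 deposited barcodes with tag G13, 23 were removed by the filters and 368 were neuron-like. Of 353 barcodes with tag G1, 347 were other main-population cells, as were 413 of 417 with tag G16 and 869 of 894 with tag G2.

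Genes with at least 20% of their UMIs in 1 cell were more frequent at P24-30, with 185 of 10821 genes, than at P12, with 19 of 10461. The proton-pump gene Atp6v1g2 had 1563 of its 1713 UMIs in a cell of 1970 UMIs, and the RNA-binding gene Rbm6 1000 of 2498 in a cell of 1556.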
